A study of Homo sapiens with 8 samples.

How the data were processed

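Neuroblastoma cells were transfected with a control or with small interfering RNA against TRMT6, in 2 replicates each, per the labels. Polyadenylated RNA was fragmented, part of it was kept as input, and the rest was immunoprecipitated with an antibody against N1-methyladenosine (m1A), per the labels' protocols. The labels give 4 groups of 2 samples: control input, control m1A, siTRMT6 input and siTRMT6 m1A. They do not say whether the replicates were separate cultures, so p-values of tests between libraries measure only the spread between these libraries, which may be technical. The p-values of gene lists, of direction splits, of chromosomes, of neighbouring positions and of read percentiles come from genes or positions. They do not measure the spread between replicates. Cells are named SK-N-BE in the sample titles and SK-N-AS in the source field, the cell line field and the design text.

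The values came from 1 deposited table of 25539 lines, which named 9962 single-base positions once for each of 12150 transcripts. Per the submitters' processing notes, FastQC 0.11.3 and STAR were used, with the genome build hg38. The caller of the positions, the counting rule, the treatment of reads that map to several places and the statistical test are not given in the sources used here. Per the file headers, the deposited table gave a site, a transcript region, 4 columns of counts, a log2 fold change, a p-value and an adjusted p-value. The count columns were named by condition and number, and the names do not say whether they hold m1A or input reads. Because the deposited table lists m1A sites, the counts were taken as m1A reads of the control and siTRMT6 groups. Whether the authors subtracted input counts, and whether a deposited count of 0 means no reads or no call, is not stated. Input values are not used here, so neither the TRMT6 transcript level nor a change of m1A over input was tested.

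The authors' log2 fold change was recovered from the values. It was the summed siTRMT6 reads over the summed control reads, a sum of 0 replaced by 0.5, divided by a scale of 1.14, and it matched all 9962 positions within 0.001. The authors' p-value depended only on the 2 summed counts: none of the 126 distinct pairs of sums had more than 1 p. Replicates were therefore pooled in the authors' p-values, which take no account of the spread between them. The largest deposited p-value was 0.0478, so the table had been filtered on the test before deposit. The deposited adjusted p-values imply about 20215 tests and a rank of 17323 for the largest p, more than the positions listed, and the remaining positions are not analysed here. With that rank, tested positions with a p no larger than 0.0478 are missing too, for a reason that is not given. In 15 places the adjusted p fell while p rose, so these values are not standard Benjamini-Hochberg values. Sites were listed counting from 0, as the transcript coordinates of the 10 mitochondrial positions showed, and are given here counting from 1.

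The libraries held 8655 (control 1), 46007 (control 2), 40771 (siTRMT6 1) and 13812 (siTRMT6 2) reads at listed positions, with a median of 8 or 9 reads per position. The smallest count listed alone was 5 in a control library and 6 in a siTRMT6 library. These totals cover the listed positions only and are not the sequencing depth of the libraries. Intervals of shares of positions are 95% Wilson intervals. They cover counting error only, since positions of 1 library or gene are not independent. Ranges after the mean of random lists or permuted labels are the central 95% of those lists or permutations, unless stated. Reads without molecular identifiers are also not independent molecules.

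The main test of the 4 count columns was edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its minimum count of 10, and the quasi-likelihood test of siTRMT6 against control, with Benjamini-Hochberg adjustment at 0.05. The planned interaction of condition with immunoprecipitation could not be fitted without input values. TMM found too few positions shared between libraries to compare them, and returned scaling factors with warnings. Folds at positions where a group had no reads are set against a floor of 3 counts over that group, scaled by the reads at listed positions. They are lower bounds only if a deposited 0 means no reads, which is not known. DESeq2 1.42.0 was an alternative. In counts simulated from the gene totals, with 200 genes drawn to change before filtering, the edgeR steps recovered 6% of the genes changed 2-fold (915 genes tested), 26.9% of those changed 4-fold (1007 genes) and 98.6% of those changed 8-fold (1015 genes). They made 0, 0 and 3 false calls. The simulated dispersion was 0.05, far below the estimated common dispersion of 2.60 for genes and 1.75 for positions. The simulated counts also lacked the selection on pooled p-values. These rates therefore do not carry over to the position calls. The neighbour and gene list tests were also tested on simulated data.

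Further steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Neighbouring positions were paired along each chromosome, and their library labels were permuted 1000 times. Pairs from different libraries were also counted in windows of 50 nt, and positions at 0 in the other replicate were compared with the share of zeros that Poisson counting gives. Positions within 50, 100, 200 or 500 nt of each other were also joined into regions and their reads summed. Regions of transcripts came from the table, with 5' UTR before coding sequence, 3' UTR and non-coding RNA when transcripts differed. Of 4945 gene symbols, 4338 matched the GRCh38.p14 reference as written, 285 by an older symbol and 4 as mitochondrial genes; 318 had no match. Gene lists were compared with 10000 random lists of protein-coding genes (20050 in the reference) matched in 10 groups of gene span, and adjusted over the lists; lists with under 5 members in that background had no such test. Gene span stood in for exonic length, and any listed transcript for the longest one. The smallest p that the random lists could give was 0.0002 and that of the label permutations 0.001, or 0.002 in a two-sided test. Two-sided exact permutation tests of 2 libraries against 2 could not go below 0.333.

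The gene lists, the main test of each planned comparison and the naming rule were chosen before the data were examined; the tests of neighbouring positions, of reads in the other replicate and of read percentiles were chosen after. The rule named TRMT6, TRMT61A and SST, then the members with a position in the lists of m1A enzymes and readers, neuropeptides and earlier described m1A transcripts. It also named the 10 positions with the smallest p, the 10 largest gains and 10 largest losses, and up to 4 members of each other list, by smallest p. Some members that this rule names are not reported here. The 22 positions called by edgeR, the positions with reads in both conditions, and GATA3, HAND2, DBH, TH and the genes with the most positions were named after their values were seen. Alternatives chosen in advance were a stricter threshold (p below the median of 0.00369), no filter on low counts, DESeq2, a replicate block, leaving out each library for the overlap and the edgeR calls, random lists without length matching, other distances from the transcript start and other thresholds. Joining of positions, sums per gene, equal library sizes, lists restricted to positions seen in both replicates, 1 position per gene, scaling of joined positions by listed reads, the neighbour tests and leaving out each library elsewhere were added after the data were seen. Motif, GC content, random placement and start or stop codon distance need a genome or transcript models and were not run.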

Results

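TRMT6 is the non-catalytic partner of TRMT61A in the enzyme that places m1A in tRNA and in tRNA-like stems of some other RNAs. The series silenced TRMT6 in neuroblastoma cells and asked where m1A on mRNA then differed; its title names SST, the precursor of somatostatin, and YTHDF2, a reader protein of methylated RNA. The values analysed were reads at 9962 positions in 4945 genes, from 2 control and 2 siTRMT6 libraries taken as m1A immunoprecipitates. Control 1 had reads at 819 positions in 794 genes, control 2 at 4269 positions in 3308 genes, siTRMT6 1 at 3607 positions in 2796 genes and siTRMT6 2 at 1414 positions in 1243 genes. Summed by condition, the controls held 54662 reads and the siTRMT6 libraries 54583. Of the positions, 98.6% had reads in 1 library, 133 positions in 2, 7 in 3 and none in all 4.

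**Figure D1:**
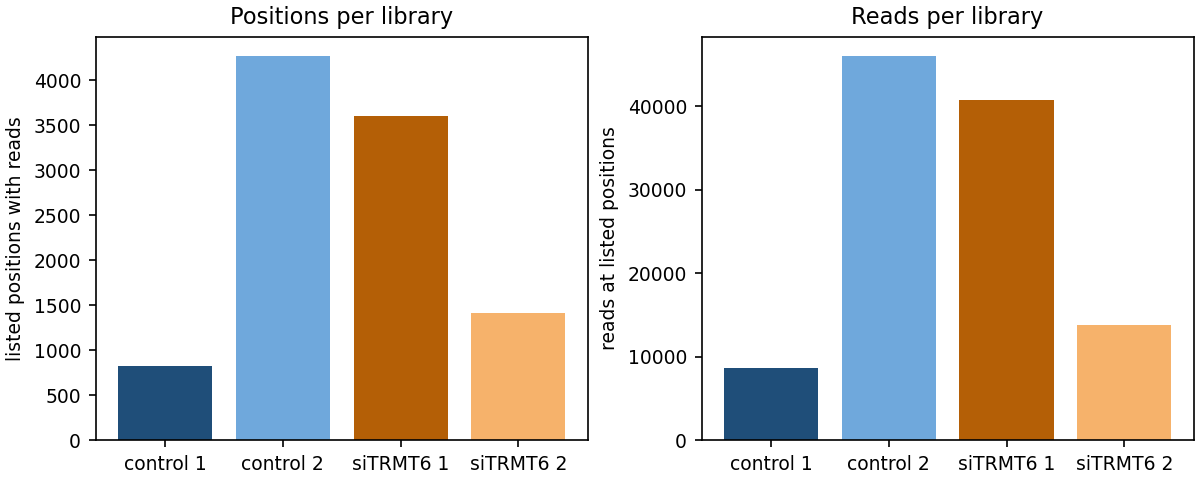
Listed positions with reads (left, number of positions) and reads at those positions (right, number of reads) in each of the 4 libraries. Control 2 held 46007 reads at 4269 positions and control 1 held 8655 reads at 819 positions, while the sums by condition were 54662 and 54583 reads.

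TRMT6 itself had no listed position, nor had SST, so neither the silenced gene nor the gene in the series title could be followed in these reads. TRMT61A, the catalytic subunit, had 4 positions on chromosome 14: 9 reads at 103535576 (3' UTR) and 8 at 103530097 (coding sequence) in control 2, and 10 reads at 103534990 (3' UTR) and 8 at 103530112 (coding sequence) in siTRMT6 1. The coding positions lay 15 nt apart. YTHDF2 had 6 reads in siTRMT6 1 at each of 28743407 and 28743762 on chromosome 1, both in coding sequence. The authors' deposited table gave the YTHDF2 positions a log2 fold change of 3.40 (adjusted p = 0.0376). The authors' deposited table gave the 4 TRMT61A positions values from -4.35 to 4.14.

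Among the other m1A enzymes and readers, FTO (a demethylase) had 8 reads in control 2 and 14 in siTRMT6 1 over 3 positions, and PRORP (a subunit of mitochondrial RNase P) had 14 and 7 over 3 positions. TRMT10C, its methyltransferase partner, had 6 reads in control 2. TRMT61B, which methylates mitochondrial RNA, had 5 reads in control 1 and 6 in control 2 at different bases, and the demethylase gene ALKBH1 had 5 in control 2. The reader YTHDF3 had 7 reads in siTRMT6 1. In all, 8 of the 17 members of this list found in the background had a position, against 3.82 (1 to 7) in random lists matched on gene span (adjusted p = 0.0524). Without control 1 the adjusted p was 0.0426 and without siTRMT6 2 it was 0.0382, while the list had 6 genes without control 2 (adjusted p = 0.111) and 6 without siTRMT6 1 (adjusted p = 0.167). At the stricter threshold the list had 1 gene against 2.06 in random lists (adjusted p = 0.875).

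The neuropeptide list, which holds SST, its receptors and secretory granule genes, had 4 of 26 members with a position, against 5.21 (2 to 9) in random lists (adjusted p = 0.760). SCG2, a granin of secretory granules, had 26 reads in control 2 at 223599224 and 27 in siTRMT6 1 at 223599193 on chromosome 2, and 21 in control 1 at 223598830. SCG3 had 31 reads in control 2 and 6 in siTRMT6 1 over 5 positions. NPY, encoding neuropeptide Y, had 11 reads in siTRMT6 1, and ADCYAP1, encoding the peptide PACAP, had 9 in control 2.

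Mitochondrial transcripts held the highest counts in each library. In MT-CO2, a subunit of cytochrome c oxidase, control 1 had 220 reads at position 8103 of chromosome M, control 2 had 193 at 8033, siTRMT6 1 had 221 at 8025 and siTRMT6 2 had 144 at 7987. Each of these bases had reads in 1 library. The authors' deposited table therefore gave log2 fold changes of -8.97, -8.78, 8.60 and 7.99 within 1 stretch of the same mRNA. Summed from 7987 to 8103 and scaled as the authors' deposited table is, the log2 value was -0.36. Scaled by the listed reads of each condition, each summed log2 given here is 0.19 higher, and that of MT-CO2 was -0.18. MT-RNR2, the large mitochondrial ribosomal RNA, had 140 reads at 2748 in control 1, 122 at 2693 in control 2 and 131 at 2550 in siTRMT6 1, with a summed log2 of -1.18. MT-ND6, a subunit of respiratory complex I on the light strand, had 189 reads at 14616 in siTRMT6 1 and 128 at 14593 in siTRMT6 2, and no control reads at a listed position. MT-ND5, another subunit of that complex, had 150 reads at 13134 in siTRMT6 2. Reads of nuclear copies of mitochondrial DNA could not be set apart.

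Outside the mitochondrion, IGF2, a fetal growth factor, had 73 reads in control 2 at 2132498, 68 in siTRMT6 1 at 2132516 and 46 in siTRMT6 2 at 2132469, all in its 3' UTR on chromosome 11, and 66 in siTRMT6 1 at 2130407. The first 3 bases together had a log2 of 0.46. CHGA, encoding the granule protein chromogranin A, had 62 reads in control 2 at 92935113 (3' UTR, chromosome 14) and 35 in siTRMT6 2 at 92935086, a summed log2 of -1.01, and 61 in siTRMT6 1 at 92931669 in coding sequence. NEFM, a neurofilament subunit, had 65 reads in siTRMT6 1 at 24914716 on chromosome 8 and 60 in control 2 at 24914733, with a summed log2 of -0.069 on the authors' scale and 0.12 on that of the listed reads; the first of these bases was also listed for a transcript on the other strand. MKI67, a marker of dividing cells, had 62 reads in control 2 at 128105312 on chromosome 10. Across all positions, the authors' deposited table called 4937 higher and 5024 lower at an adjusted p below 0.05. Those calls compare pooled reads, and 9822 of the positions rest on 1 library.

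**Figure D2:**
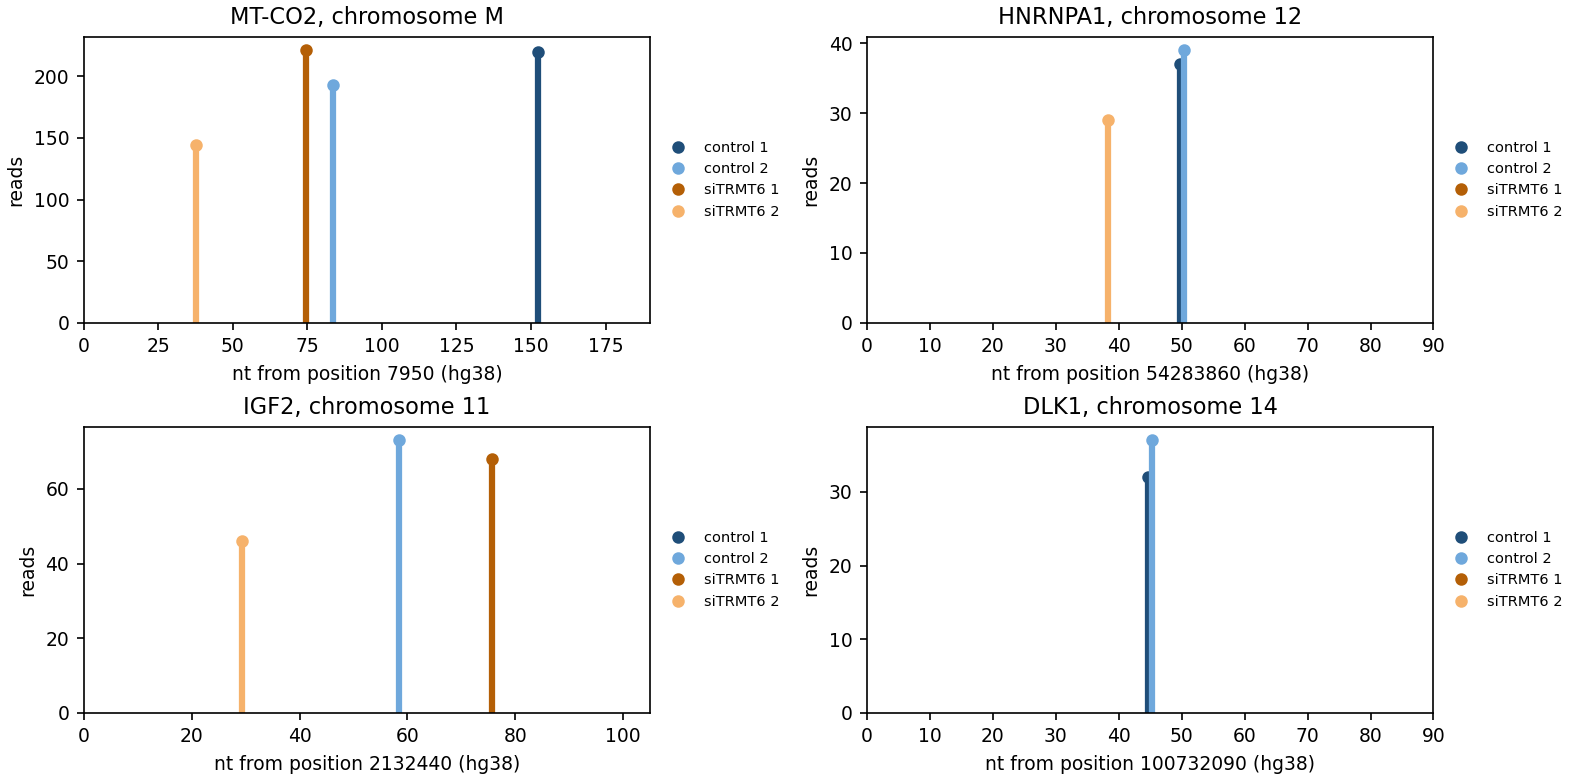
Reads (vertical axis) at listed positions (horizontal axis, nt from the stated hg38 base) in MT-CO2, HNRNPA1, IGF2 and DLK1, with 1 stem per library and stems at the same base drawn side by side. In MT-CO2 the 4 libraries have 220, 193, 221 and 144 reads at 4 bases, while in DLK1 both controls have reads at the same base, 32 and 37.

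When the 4 libraries were tested as replicates with edgeR, 34 positions passed the filter on low counts and 22 were called, 13 higher and 9 lower in siTRMT6. With equal library sizes in place of TMM, 29 of 37 were called, 10 higher and 19 lower. Folds written as "at least", here and below, are lower bounds only if the group without listed reads truly had none at that base. Whether it had none is not known. The higher positions included ELAVL3, a neuronal RNA-binding protein, with 26 and 17 reads in the siTRMT6 libraries at 11453823 of chromosome 19 (3' UTR) and none in the controls, at least 14.4-fold. SHD, an adaptor protein, had 24 and 10 reads at 4283184 of chromosome 19, at least 11.3-fold higher. KAT6A, a histone acetyltransferase, had 20 and 13 reads at 41933394 of chromosome 8, and ARID1A, a SWI/SNF chromatin remodelling subunit, had 16 and 10 at 26774963 of chromosome 1, at least 11.02-fold and 8.68-fold higher. SETD1A, a histone methyltransferase, had 15 and 9 reads at 30979229 of chromosome 16, and ASXL1, a Polycomb-associated protein, had 16 and 11 at 32434835 of chromosome 20. UNC13A, which primes synaptic vesicles, had 20 and 12 reads at 17603664 of chromosome 19 (3' UTR). The transcriptional coactivator gene ZMIZ1 had 18 and 12 at 79298554 of chromosome 10, and the ubiquitin ligase gene MGRN1 had 16 and 8 at 4690768 of chromosome 16.

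Of the 9 lower positions, DLK1, a Notch-family ligand made by chromaffin-lineage cells, had 32 and 37 reads in the controls at 100732135 of chromosome 14 and none in the siTRMT6 libraries, at least 22.97-fold lower. ISLR, a leucine-rich repeat protein, had 30 and 32 reads at 74175507 of chromosome 15, at least 20.6-fold lower. PRPH, the neuronal intermediate filament peripherin, had 28 and 33 reads at 49297547 of chromosome 12, at least 20.3-fold lower; the position was listed on both strands because an antisense transcript overlaps it. GSE1 had 25 and 28 reads at 85654393 of chromosome 16, although 8 of its 15 positions were higher, 1 of them with 12 and 6 siTRMT6 reads at 85648698. FADS2, a fatty acid desaturase, had 20 and 21 at 61867263 of chromosome 11 (3' UTR), and PRDX5, a peroxiredoxin, had 17 and 20 at 64318348 of the same chromosome. The GSE1, FADS2 and PRDX5 positions with control reads were at least 17.6-fold, 13.6-fold and 12.3-fold lower. All these folds hold only if the siTRMT6 libraries truly had no reads at these bases, which is not known. Their scaling by listed reads is also uncertain. The ratio of control 1 to control 2 was 0.188 in listed reads and 0.868 at the bases they shared.

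Of the 22 called positions, 18 lay in genes that also held a listed position of the opposite direction, such as ELAVL3 with 30 reads in control 2 and PRPH with 68 in siTRMT6 1, and 4 did not (KAT6A, UNC13A, MGRN1 and ISLR). For 7 of the 22, a position listed in the opposite direction lay within 200 nt. HNRNPA1, a splicing regulator, had 37 and 39 control reads at 54283910 of chromosome 12, at least 25.3-fold lower, but siTRMT6 2 had 29 reads 12 nt away, and the summed log2 was -1.57. EIF5A, a translation factor, had 27 and 28 control reads at 7309746 of chromosome 17 beside 29 siTRMT6 reads at a distance of 5 nt (summed log2 -1.11), and U2AF2, a splicing factor, had 16 and 18 at 55669664 of chromosome 19 with a summed log2 of -1.95. Among higher positions, RPL36, LARP1, KMT2D and FBXW4 had control reads 31, 12, 28 and 18 nt away, and summed log2 values of 0.32, -0.31, 0.31 and 0.43; for LARP1 the edgeR value of the joined region was 0.13, of the other sign. HNRNPA1, EIF5A and RPL36 have near-identical pseudogenes, so their read numbers are uncertain.

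The adjusted edgeR p of the 22 calls ran from 0.00592 to 0.0134, and each had reads in both replicates of 1 condition and none in the other; the 12 tested positions that were not called had reads in both conditions. The filter selects this pattern from a table already selected on pooled p-values, so these p-values are too small as evidence for single genes. Replicate counts at shared bases also differed by less than sampling noise (chi-square over degrees of freedom 0.1005 in the controls and 0.140 in the siTRMT6 libraries). Their closeness at the called positions is therefore not independent support. No call was left without the filter (0 of 9962 in edgeR, 0 at an unadjusted p under 0.05), with DESeq2 (0 of 34, 14 unadjusted), or when control 1, control 2, siTRMT6 1 or siTRMT6 2 was left out (0 calls each in edgeR; 5 positions at an unadjusted p under 0.05 without siTRMT6 1, and 0 without each of the others). Summed per gene, edgeR called 0 of 975 genes (126 at an unadjusted p under 0.05), and DESeq2 called 1, MT-ND6 (adjusted p = 0.0198), with 45 unadjusted.

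**Figure D3:**
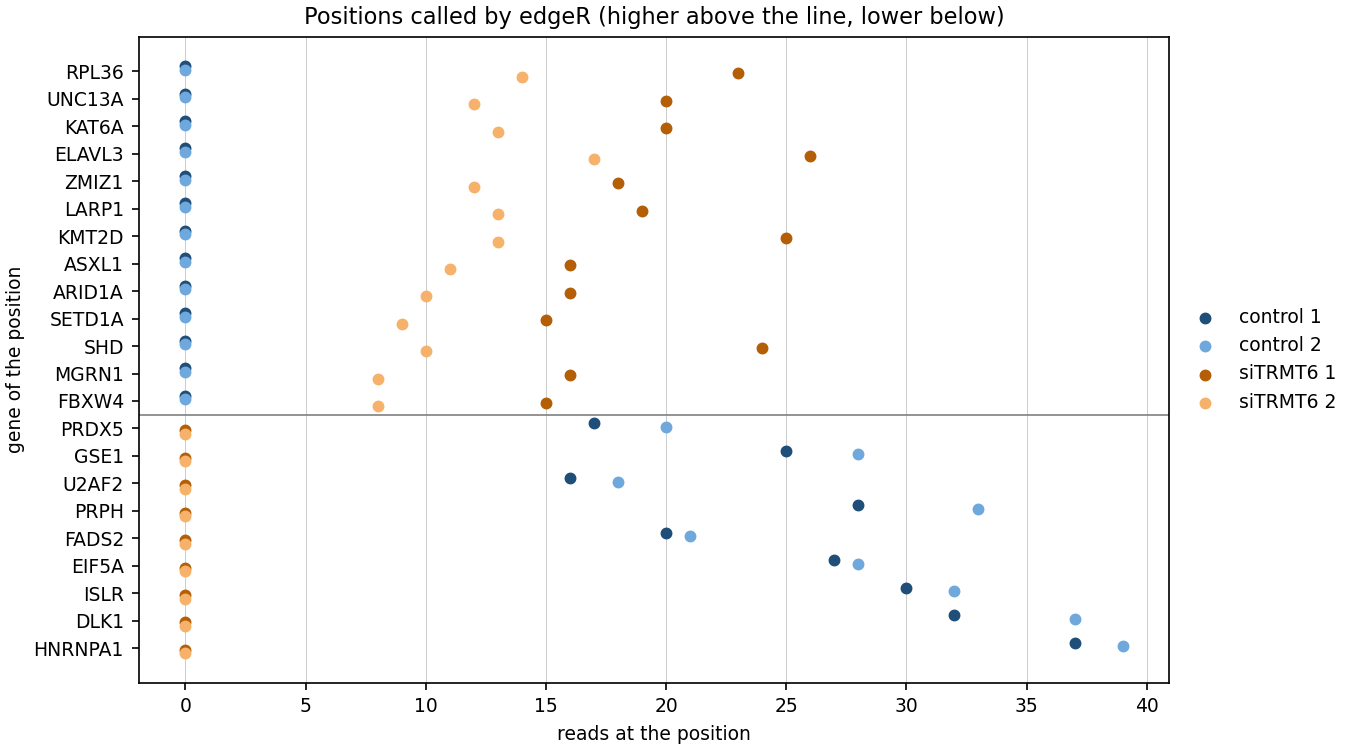
Reads (horizontal axis, number of reads) in each of the 4 libraries at the 22 positions called by edgeR, labelled by gene on the vertical axis. The 13 higher positions lie above the line and have 0 reads in both controls, and the 9 lower positions lie below it and have 0 reads in both siTRMT6 libraries.

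Control and siTRMT6 libraries rarely had reads at the same base. Only 14 of 5025 control positions (0.279%, Wilson interval 0.166 to 0.467) had siTRMT6 reads, and PHOX2A, HAND2 and DBH of the adrenergic list were among their genes. Without control 2 the share was 0.977%, and without siTRMT6 2 it was 0. Part of this low share follows from the filter on the authors' pooled p, since a base with similar reads in both conditions would not be listed. PHOX2A, a homeodomain factor of noradrenergic neurons, had 57 reads in control 1 and 24 in siTRMT6 2 at 72239875 of chromosome 11. HAND2, a transcription factor of the same lineage, had 56 reads in control 2 and 29 in siTRMT6 2 at 173529365 of chromosome 4 (5' UTR), and DBH, which makes noradrenaline, had 17 and 7 in those libraries at 133651754 of chromosome 9. None of these positions was called by edgeR (adjusted p = 0.957 for PHOX2A and DBH, 0.982 for HAND2). Replicates shared few bases too: 63 in the controls, 7.69% of control 1 and 1.48% of control 2, and 70 in the siTRMT6 libraries.

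Joining positions within 200 nt gave 8005 regions, of which 1374 held both conditions, 28.5% of the control regions, and 13 held all 4 libraries. In the regions with both conditions the median log2 on the authors' scale was -0.34 (quartiles -0.64 and -0.09), and 166 differed by at least 2-fold. Scaled by listed reads, the median was -0.15 (quartiles -0.46 and 0.10) and 85 differed by at least 2-fold. These regions were chosen because both conditions had a listed position, with a median of 8 or 9 reads in each library. The selection itself favours ratios near 1, so these values do not show that changes were small. Within 200 nt, library pairs of the same condition shared on average 32.4% of the smaller set and pairs of different conditions 23.7% (exact permutation p = 0.333, the smallest that 3 splits allow). Each pair of the same condition set a small library against a large one. The smallest libraries, control 1 and siTRMT6 2, shared 16.2%, and the other pairs of different conditions 24.6% to 27.1%. Library size may therefore add to the gap. Of 1914 neighbouring pairs within 200 nt, none came from 1 library, against 33.6% with permuted labels (permutation p = 0.001, the smallest possible). Pairs from different libraries shared their condition in 25.7% of cases, against 24.6% (22.3 to 27.1) with permuted labels (permutation p = 0.406). Over 6 separate distance ranges, the share passed the threshold at 51 to 100 nt, with 35.1% against 24.5% (permutation p = 0.00599, adjusted 0.03), and beyond 500 and up to 2000 nt, with 29.8% against 24.7% (permutation p = 0.00999, adjusted 0.03).

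**Figure D4:**
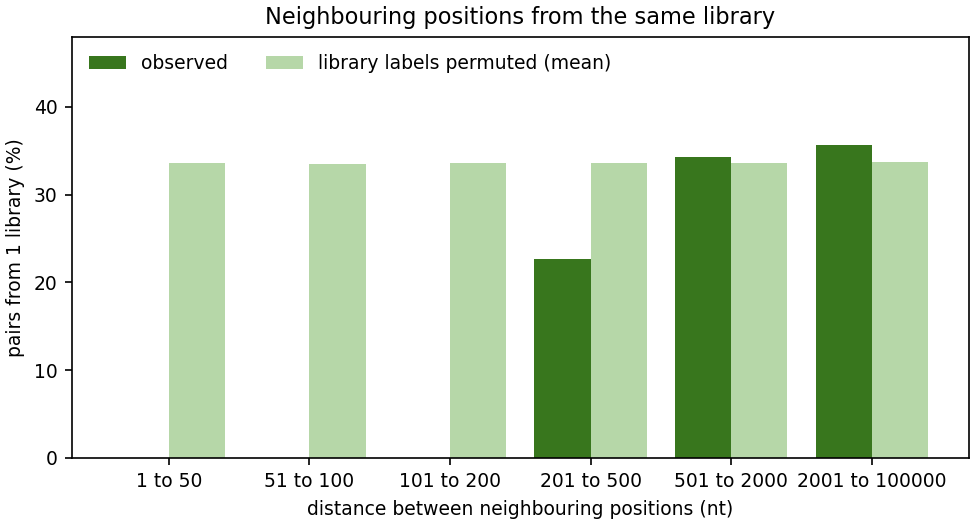
Share of neighbouring position pairs that came from 1 library (vertical axis, percent) by distance (horizontal axis, nt), as observed and as the mean of 1000 permutations of the library labels. No pair within 200 nt came from 1 library, while beyond 500 nt the shares were 34.3% and 35.7%, close to the permuted 33.6% and 33.7%.

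Genes of the noradrenergic state of neuroblastoma were among the most often listed. Of 30 adrenergic genes, 21 had a position, against 6.66 (3 to 11) in random lists (adjusted p = 0.0004), with 50 positions higher and 35 lower. Without control 2 the list had 50 higher and 11 lower (82.0% higher, against 85.7% of the other positions). Without siTRMT6 1 it had 19 higher and 35 lower (35.2% higher, against 21.7%). Leaving out a control library removes only lower positions, and leaving out a siTRMT6 library only higher ones. These splits therefore cannot show an effect of silencing on this list. MYCN, the oncogenic transcription factor amplified in many neuroblastomas, had 50 reads in control 1 at 15942821 and 53 in control 2 at 15942824 of chromosome 2, 48 in siTRMT6 1 at 15945985, and 29 and 30 in siTRMT6 2 at 15945981 and 15942270. PHOX2A had 50 reads in control 2 at 72244073 and 49 in siTRMT6 1 at 72244098 in its 5' UTR. TBX2, a T-box factor, had 30 reads in control 2 at 61405510 of chromosome 17 and 29 in siTRMT6 1 at 61405516. Of 36 mesenchymal genes, 11 had a position, against 7.96 (3 to 13; adjusted p = 0.353). TWIST1 had 16 reads in control 1 and 21 in siTRMT6 1, JUNB had 17 in control 2 and 9 in siTRMT6 2, SOX9 had 10 in control 2 and 13 in siTRMT6 1, and VIM, which encodes vimentin, had 9, 12 and 11 reads in control 1, control 2 and siTRMT6 2.

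The translation machinery was listed widely. Of 83 cytosolic ribosomal protein genes, 54 had a position, against 15.4 (9 to 22; adjusted p = 0.0004), with 81 positions higher and 58 lower. RPS2 had 34 reads in control 2 at 1964748 of chromosome 16 and 23 in siTRMT6 2 at 1964736, and RPS7 had 23 reads in control 1, 16 in control 2 and 14 in siTRMT6 1 over 3 positions. Of 35 translation factors, 25 had a position, against 8.01 (3 to 13, adjusted p = 0.0004), with 47 higher and 33 lower. The split was 47 higher and 8 lower without control 2 (85.5% higher, against 85.7% of the other positions). It was 17 higher and 33 lower without siTRMT6 1 (34.0% higher, against 21.7%). Leaving out a library removes positions of 1 direction only, so these splits cannot show an effect of silencing on this list. EIF4G1, the scaffold of the cap-binding complex, had 33, 54, 22 and 24 reads in control 1, control 2, siTRMT6 1 and siTRMT6 2 over its positions, EEF1A1 had 30 in siTRMT6 1, and EIF3B had 24 in control 1, 55 in control 2 and 26 in siTRMT6 1. RPL36 and EIF5A are the members with an edgeR call. Ribosomal protein genes, histone genes, EEF1A1 and GAPDH have near-identical copies elsewhere in the genome, so their reads are uncertain, and how the authors placed shared reads is not given in the sources used here.

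Proliferation and energy genes followed. Of 39 cell cycle genes, 23 had a position, against 9.14 (4 to 15; adjusted p = 0.0004); without control 2 there were 14 (adjusted p = 0.014). Over all its positions MKI67 had 124 reads in control 2, 145 in siTRMT6 1 and 26 in siTRMT6 2, CCND1 had 112, 96 and 12 in these libraries, the mitotic kinase gene PLK1 had 20, 31, 20 and 8 in control 1, control 2, siTRMT6 1 and siTRMT6 2, and E2F1 had 13 in control 1 and 21 in control 2. Of 33 RAS and PI3K pathway genes, 16 had a position, against 7.62 (3 to 13; adjusted p = 0.0032); SPRY4, an inhibitor of the pathway, had 44 reads in control 2, AKT1 had 47 in siTRMT6 1, DUSP4 had 40 and 30 in those libraries, and EGFR had 11 in control 1, 27 in control 2 and 6 in siTRMT6 1. Of 26 glycolysis and MYC genes, 16 had a position, against 6.09 (2 to 11; adjusted p = 0.000711). TPI1 had 32 reads in control 2 and 26 in siTRMT6 1, GPI had 84 in control 2, 36 in siTRMT6 1 and 27 in siTRMT6 2, and in siTRMT6 1 and siTRMT6 2 GAPDH had 32 and 23 and ALDOA 27 and 40, with none in the controls at listed positions. Of 98 nuclear oxidative phosphorylation genes, 50 had a position, against 20.2 (13 to 28; adjusted p = 0.0004), among them NDUFV1 with 20 reads in control 2 and 18 in siTRMT6 1, COX4I1 with 15 in control 1, 32 in control 2 and 32 in siTRMT6 2, CYC1 with 32 in control 2, and NDUFS7 with 12 and 7 in the siTRMT6 libraries at 1395532 of chromosome 19.

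Of 22 stress response genes, 16 had a position, against 4.48 (1 to 8; adjusted p = 0.0004); without control 2 there were 9 (adjusted p = 0.014). The chaperone gene HSP90AB1 had 41 reads and HSPA8 had 29, both in siTRMT6 1, the transcription factor gene ATF4 had 27 in control 2, and CALR had 28 in control 2 and 33 in siTRMT6 1. Of 92 histone genes, 28 had a position, against 11.4 (6 to 18; adjusted p = 0.0004), such as H2AX with 0, 21, 16 and 10 reads in control 1, control 2, siTRMT6 1 and siTRMT6 2, H3C10 with 0, 12, 7 and 0, and H3C15 with 14 in control 2. The histone call was lost without length matching (adjusted p = 0.0871) and at the stricter threshold (adjusted p = 0.241), and without control 2 there were 16 genes (adjusted p = 0.0233). Of 23 apoptosis genes, 7 had a position, against 5.35 (2 to 10; adjusted p = 0.588), and 4 without control 2: MCL1 had 18 reads in siTRMT6 1 and 10 in siTRMT6 2, CASP2 had 9 and BCL2 had 8 in control 2, and BCL2L1 had 8 in siTRMT6 1.

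Zinc finger genes were listed less often than random lists, 92 of 517 against 124 (105 to 143; adjusted p = 0.00224). ZNF513 had 37 reads in control 2, ZNF580 had 50 in siTRMT6 1, ZNF316 had 37 in siTRMT6 1 and 22 in siTRMT6 2, and ZNF629 had 20 in control 2, 42 in siTRMT6 1 and 14 in siTRMT6 2. Olfactory receptor genes, chosen as a negative set, had 0 of 392 with a position, against 63.7 (50 to 78; adjusted p = 0.0004). Markers of Schwann, immune, endothelial, epithelial, liver and blood cells had 0 of 19, against 3.89 (1 to 8; adjusted p = 0.0339); that p was 0.111 without control 2, 0.0755 without siTRMT6 1 and 0.241 at the stricter threshold. Random lists were matched on gene span and not on expression, so these counts do not set methylation apart from transcript abundance.

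With all 4 libraries, no list differed from the other positions in its split of higher and lower positions by Fisher's exact test adjusted over the lists; the smallest adjusted p was 0.492, for the ribosomal, adrenergic and translation lists and the earlier described m1A transcripts. The ribosomal list had 58.3% of its positions higher against 49.4% of the others. These shares were 69.8% against 53.4% without control 1 and 43.1% against 21.4% without siTRMT6 1. They were 76.4% against 85.9% without control 2 and 40.2% against 41.8% without siTRMT6 2. With 1 library left in a condition, direction mostly records which library listed a position. Fisher's test also treats positions as independent, so these shares cannot show whether direction shifted with silencing. Restricted to positions with reads in both replicates of 1 condition, 2 of the 12 lists past the threshold stayed there: ribosomal proteins with 4 genes against 0.379 and oxidative phosphorylation with 4 against 0.492 (adjusted p = 0.0208 for both).

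**Figure D5:**
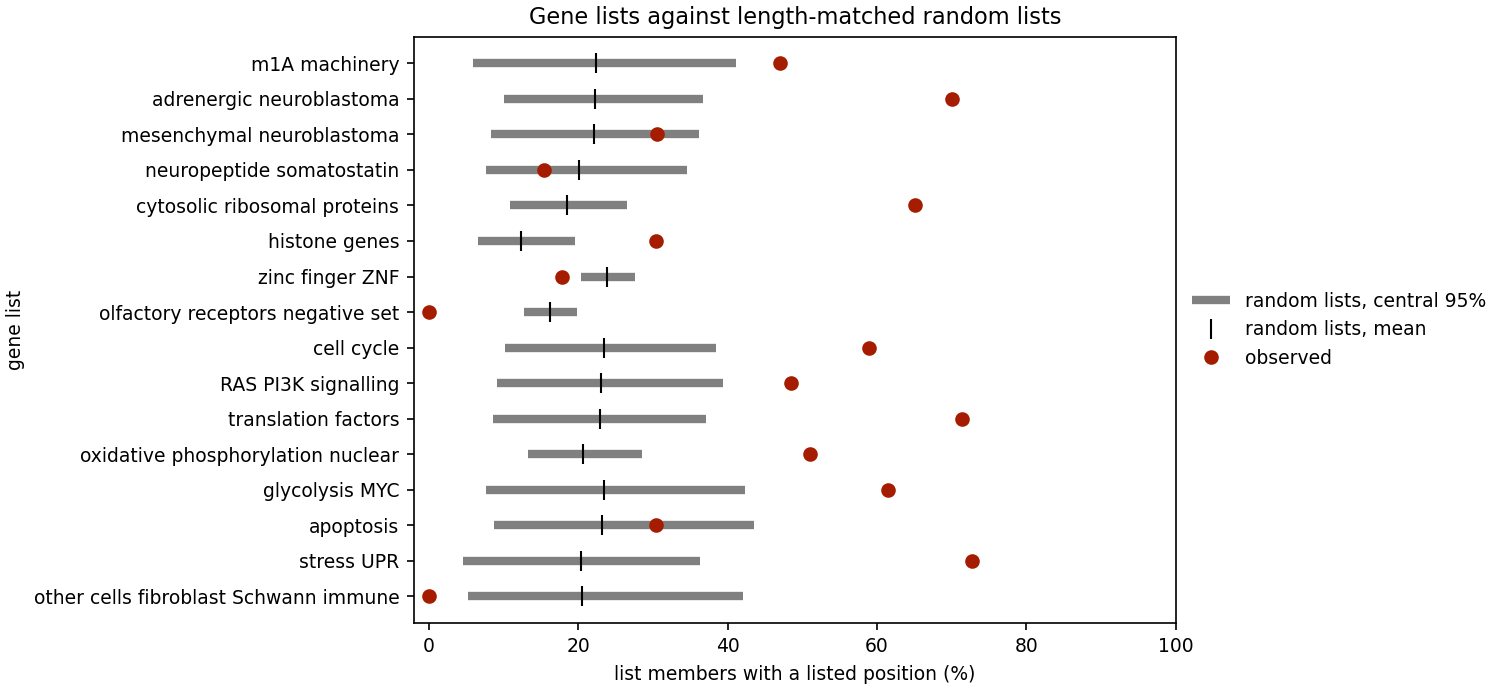
Share of list members with a listed position (horizontal axis, percent) for 16 gene lists (vertical axis), with the mean and the central 95% of 10000 length-matched random lists. Adrenergic genes (21 of 30) and ribosomal protein genes (54 of 83) lie above their random ranges, and olfactory receptors (0 of 392) lie below theirs.

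Positions lay mostly in coding sequence: 63.1% of control positions (Wilson interval 61.8 to 64.4) and 62.4% of siTRMT6 positions (61.1 to 63.8). The 3' UTR held 20.4% and 19.7%, the 5' UTR 12.8% (11.9 to 13.8) and 14.1% (13.2 to 15.1), and non-coding RNA 3.62% and 3.72%. Averaged over libraries, the 5' UTR share was 14.2% ± 2.84 (SD, n = 2) in the controls and 14.4% ± 0.671 (SD, n = 2) in the siTRMT6 libraries (exact permutation p = 1). The coding share was 63.7% ± 0.960 and 62.2% ± 0.519 (SD, n = 2 each; exact permutation p = 0.333). Without control 2 the difference of the pooled 5' UTR shares turned from 1.30 points to -2.10, and without siTRMT6 1 it was 2.09. Within 100 nt of a listed transcript's start lay 7.34% of control positions (6.65 to 8.10) and 8.12% of siTRMT6 positions (7.39 to 8.91). These shares depended on the genome strand. Coding sequence held 70.0% of plus strand and 43.4% of minus strand positions, and the 5' UTR 8.13% and 27.8%. The plus strand held 68.6% of siTRMT6 2 positions and 74.7% to 75.7% in the other libraries. The cause was not tested, so differences between libraries may carry this strand split.

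Chromosomes differed in how many positions they held for their number of protein-coding genes. Chromosome 22 had 357 positions against 225 expected, chromosome 16 had 640 against 426 and chromosome 19 had 993 against 723, while chromosome 18 had 64 against 135 and chromosome X 250 against 423. By Fisher's exact test with Benjamini-Hochberg adjustment, 18 of 23 chromosomes departed, 9 above and 9 below. Between conditions, chromosome 19 held 440 control and 554 siTRMT6 positions (adjusted p = 0.00119) and chromosome 3 held 227 and 160 (adjusted p = 0.0103). With 1 position per gene 4 chromosomes differed between conditions (smallest adjusted p = 0.00337), and at the stricter threshold 0 did (smallest adjusted p = 0.489). Positions of 1 library or gene are not independent in this test.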

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

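Joining positions, sums per gene, equal library sizes, scaling by listed reads, lists restricted to both replicates, 1 position per gene and, except for the overlap and the edgeR calls, leaving out a library were tests added after the data were seen; the others were planned. The cause was not tested unless stated. The stricter threshold left 4846 positions, and leaving out 1 library left 5762 to 9207, from fewer reads. The share of control positions with siTRMT6 reads, 0.279% at the same base, was 22.4%, 26.1% and 28.5% after joining within 50, 100 and 200 nt, and 0 to 0.977% when 1 library was left out. At an adjusted p below 0.01, the authors' deposited table held 5837 positions.

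The 22 edgeR calls became 21 at an adjusted p below 0.01 and 29 with equal library sizes. They fell to 0 without the filter (0 unadjusted), with DESeq2 (14 at an unadjusted p under 0.05), without any 1 library (0 to 0; 5 unadjusted without siTRMT6 1 and 0 otherwise; the lone library of a condition is then assumed to vary like the others), after joining within 50 nt (0 of 389; 93 unadjusted, and 0 with 20 in DESeq2) or 200 nt (0 of 492; 126 unadjusted, and 0 with 11 in DESeq2), and per gene (0 of 975; 126 unadjusted, and 1 with 45 in DESeq2). Joining left the reads of 15 of the 22 calls as they were, and their log2 sizes (6.70 to 8.001 before, 6.69 to 8.01 after joining within 200 nt) hardly moved; their adjusted p was 0.0676 to 0.0821 at 50 nt and 0.0576 to 0.0758 at 200 nt, with a common dispersion of 4.99 and 4.53 in place of 1.75. The other 7 gained reads of the opposite condition. With the replicate number as a block, 0 were called and 0 passed an unadjusted 0.05. Same-numbered libraries did not deviate together (correlation -0.031 over 4945 genes). Because 98.6% of positions had reads in 1 library, this correlation cannot exclude that the numbers pair the libraries. For single edgeR positions, 19 alternatives kept the call and 139 lost it.

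The 5' UTR difference ranged from -2.10 to 2.09 points without 1 library. The share near transcript starts, 7.74% at 100 nt, was 4.31% at 50 nt, 16.3% at 200 nt and 5.84% at the stricter threshold. With positions in both replicates, 2 lists passed in place of 12, and the adrenergic, histone, stress, m1A, mesenchymal and apoptosis lists had 0 genes. Random means for these lists were only 0.104 (m1A) to 0.249 (mesenchymal) genes, so a count of 0 shows no depletion. At the stricter threshold, lists that had not passed turned against the random mean: m1A with 1 gene against 2.06, apoptosis with 2 against 2.86 and neuropeptides with 4 against 3.23. Over all lists and alternatives, 89 kept their direction and side of the threshold, 12 lost it, 2 gained it and 9 turned. Summed over joined positions, the sign turned for MT-CO2 8025 and 7987 (-0.36), MT-RNR2 2550 (-1.18), NEFM 24914716 (-0.069), IGF2 2132498 (0.46) and MALAT1 65500804 (0.36), and 7 other named positions moved without turning. Scaled by listed reads, these were -0.18, -0.998, 0.12, 0.65 and 0.55, so the turn of NEFM comes from the authors' scale; the median of joined regions with both conditions was -0.15 in place of -0.34. The number of chromosomes that departed was 18, and 17, 18 and 14 under the alternatives. Reciprocal overlap, peak start and central 100 nt have no meaning for single bases.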

Other observations

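The tests of neighbouring positions, of reads in the other replicate and of read percentiles were chosen after the values had been seen. The long non-coding RNA and mitochondrial lists were fixed before the data were examined.

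Long non-coding RNAs carried many reads. Of 18 on the list, 10 had a position, and the median score percentile of those genes was 84.0 (adjusted p = 0.0294 against random gene lists); 16 positions were higher and 12 lower. MALAT1, a nuclear RNA of speckles and an earlier described m1A transcript, had 63 reads in control 2 at 65500804 of chromosome 11, 55 in siTRMT6 1 at 65500873 and 37 in siTRMT6 2 at 65500777, with a summed log2 of 0.36. It also had 48 reads at 65499261 and 45 at 65505221 in siTRMT6 1. MEG3, an imprinted RNA next to DLK1, had 55 reads at 100829598 and 54 at 100848103 of chromosome 14 in control 2, 46 at 100836199 and 41 at 100848802 in siTRMT6 1, and 24 in siTRMT6 2 at 100848088. NEAT1, the scaffold of paraspeckles, had 33 reads in control 1, 93 in control 2 and 38 in siTRMT6 2 over its positions, and NORAD had 20 in control 2. Of the 3 earlier described m1A transcripts on a list, MALAT1 and MT-ND5 had positions, 6 higher and 1 lower in all, and PRUNE1 had none. Of 15 mitochondrial genes, MT-CO2, MT-ND6, MT-RNR2 and MT-ND5 had positions.

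Among the genes with the most positions, DYNC1H1, the dynein heavy chain, and SPTBN1, a spectrin, had 19 each (9 higher and 10 lower), SMARCA4, a SWI/SNF ATPase, had 18 (9 higher and 9 lower) and PRRC2B had 16 (10 higher and 6 lower). Of 2521 genes with more than 1 position, 1929 (76.5%) held both directions, against 1718 (1619 to 1774) with permuted labels (permutation p = 0.002). By score percentile, adrenergic genes stood at a median of 90.9 and ribosomal protein genes at 78.5 (adjusted p = 0.0014 for both), translation factors at 76.9 (adjusted p = 0.0131) and stress genes at 77.5 (adjusted p = 0.0375). Of positions listed on 1 strand, 74.2% lay on the plus strand, where 8.13% were in 5' UTRs, against 27.8% of minus strand positions. At bases shared by replicates, counts differed by less than sampling noise (chi-square over degrees of freedom 0.1005 in the controls and 0.140 in the siTRMT6 libraries). The controls had 660 and 760 reads at these bases, although their listed totals were 8655 and 46007. Independent read counts would not lie this close, and the cause was not tested. The 22 edgeR calls lie at such bases, so the closeness of their replicates is not independent support.

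Higher and lower positions lay side by side, as in MT-CO2, IGF2 and HNRNPA1: 28.9% of lower and 30.5% of higher positions had an opposite one within 200 nt. A candidate explanation is that 1 position was placed per region in each library: no 2 positions of 1 library lay closer than 317 nt, although positions of different libraries lay as close as 1 nt. Correlated reads of neighbours are no evidence for it, since Spearman's rho was 0.74 within 200 nt, 0.57 beyond 200 and up to 500 nt, 0.67 beyond 500 and up to 2000 nt, and 0.28 farther apart. An effect of TRMT6 silencing and placement alone cannot be told apart by how often close pairs from different libraries shared their condition: 25.7% did within 200 nt, against 24.6% (22.3 to 27.1) with permuted labels, and 35.1% against 24.5% at 51 to 100 nt (adjusted p = 0.03). ISLR had 1 listed position, with reads in both controls and none in the siTRMT6 libraries, while DLK1 also had 2 higher positions and GSE1 had 8.

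Most positions had no reads in the other replicate. A difference in depth as the whole cause would leave the deeper replicate, whichever it is, with reads at most positions of the other, but 92.3% of control 1, 98.5% of control 2, 98.1% of siTRMT6 1 and 95.05% of siTRMT6 2 positions were at 0 in the other replicate. Poisson counting gives zeros at 19.6% of control 2 positions (1.24% from 20 reads up, where 97.8% were at 0) and 5.41% of siTRMT6 1 positions at the ratio of listed reads, and at 0.292% of control 2 positions at the ratio of shared bases, so for control 2 positions depth as a smaller part of the cause and a true absence cannot be told apart while the depth ratio is not known. A shift of the listed base may account for the 37.0% of positions seen in 1 library that had another library in the same joined region, since pairs from different libraries were 4.57 times as many at 1 to 50 nt (1578) as at 51 to 100 nt (345), but sites that differ between libraries by a few bases would give the same. For the other 63.0%, a shift and a true absence cannot be told apart, because positions outside the table are not analysed here, and no biological explanation was tested for this pattern.

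Adrenergic genes and MYCN ranked high in reads, while the labels name SK-N-BE, a line with MYCN amplification, and SK-N-AS, a line without it. MYCN had 210 reads, rank 20 of 4945 genes and percentile 99.6, with 50, 53, 48 and 59 reads in the 4 libraries; GATA3 had 161 reads, DBH had 91 and TH had 26, fewer than the mesenchymal genes TWIST1 (37) and VIM (32), and IGF2, on neither list, had 302 (rank 6). MYCN was presumed to lie low in the cells named in the source field, and it ranked high. That presumption was written after its reads had been seen, so the rank cannot decide between the labels. Adrenergic members with a position had a median read percentile of 94.0 and mesenchymal members 55.4, a difference of 38.6 points (21 and 11 genes; permutation p = 0.0013), which is consistent with the cells named in the titles. Reads after immunoprecipitation are not expression, and MYCN copy number is not analysed here, so this stays a hypothesis and no biological explanation was tested.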
